A study of Schizosaccharomyces pombe with 8 samples.

How the data were processed

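The series holds 8 tiling arrays of fission yeast (Schizosaccharomyces pombe) on which DNA immunoprecipitated with Rad52, a central protein of homologous recombination, was hybridised together with its input DNA. Per the labels, all strains carried the temperature-sensitive cdc25-22 allele, were grown at 25 °C, held for 4 h at 36.5 °C and returned to 25 °C, with no hydroxyurea added after release. The 4 strains were the cdc25-22 control (called WT in the labels) and the same background with rad3 deleted (rad3D), with rif1 deleted (rif1D) or with both deleted (rif1D_rad3D, the double mutant). Each strain had 2 arrays, numbered as replicates in the labels. The time between release and harvest is not given in the sources used here. The labels name total RNA and an RNA protocol as the material, whereas the series title and channel names describe immunoprecipitated and input DNA, and the values were treated as the latter. The labels do not say whether the arrays of a strain came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

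The scanner output was read as deposited, 1 file per array. Per the submitters' processing notes and the file headers, the images were quantified with Agilent Feature Extraction 10.7.3.1. Per the file headers, the authors' processed signal of each channel is an intensity after background subtraction, detrending and a linear dye factor, with no lowess term, and with no scaling between arrays. The deposited log10 ratio of red over green equalled log10 of the processed red over green signal within 1e-04 for at least 98.8% of probes on every array; it served to check the channels, and its sign was turned by computing IP over input. Per the labels, the input carried Cy5 (red) and the IP carried Cy3 (green) on every array. The series design describes the input as reciprocally labelled, but no array had the dyes the other way round, so a dye effect does not cancel within a strain and is shared by all strains. The deposited background and median spot intensities and the deposited outlier, saturation and background flags were used as described next.

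The log2 ratio of processed IP signal over processed input signal was computed per probe. Of 42,707 genomic probes, 41,933 with input signal well above background on all 8 arrays were used and 774 were left out, since input marks whether the sequence was present. Spots with outlier flags in either channel were set to missing and saturated spots were kept. Each array was centred on its median, so 0 is the typical probe of that array and only unequal change along the genome can be seen, with no loess or quantile step. Probes were averaged in windows of 1 kb with at least 2 probes, which gave 12,033 windows; the median probe spacing was 265 bp. The number of arrays, not the number of probes, limits the precision.

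Positions are those of the array design, whose header names the build Spombe:NCBI:Feb2002. The annotated reference was ASM294v3. GC content of the reference at the probe positions was correlated with the input signal of the probes in blocks of 200 kb: in 55 of 64 blocks the correlation near the stated position was above that at nearly all shifts of 1 kb or more, and the other 9 blocks lay at the right end of chromosome I from 3,800,001 on. In each of these 9 blocks the correlation was highest at a shift of 6,100 or 6,150 bp (0.158 to 0.361), but no shift was applied. The reference annotation was used only for chromosomes II, III and M and for chromosome I up to 3,750,000. The 6,063 probes beyond that point were analysed by their stated position with no gene name. Gene values were the mean of at least 2 probes whose centre lay in the gene or within 500 bp of it, for 4,790 genes.

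Differences were tested with limma, with 1 mean per strain over all 8 arrays, no covariate, a shared spread with 4 residual degrees of freedom, empirical Bayes moderation (prior degrees of freedom 7.25 for windows and 4.38 for genes) and two-sided p-values adjusted by the Benjamini-Hochberg method over all windows or genes. A window passed at an adjusted p under 0.05. A window was called enriched in a strain when it passed against 0 and its mean ratio was at least 1.5-fold. The 5 comparisons were each mutant against WT and the double mutant against each single mutant. The interaction tested whether rif1 deletion had a different effect, on the log2 scale, with and without rad3. Lists of genes or regions were tested with limma's fry, which tests whether the members of a list move, on balance, in one direction, with Benjamini-Hochberg adjustment over the lists of a comparison; camera was run as an alternative. The 20 lists tested were subtelomeres (100 kb), chromosome III ends, centromeres, the mating-type region, mitochondrial DNA, AT-rich islands (at least 72% AT), convergent and divergent intergenic regions, tRNA genes, 5S rRNA genes, snRNA and snoRNA genes, LTR and Tf2 elements, wtf genes, ribosomal protein genes, abundantly transcribed genes, histone genes, G1/S genes, heat-shock genes, meiotic genes and long genes. The list of centromeres held those of chromosomes II and III only. A list of annotated replication origins had 0 members in the reference and could not be tested.

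The strains, comparisons, tests, lists, alternatives and the rule for naming regions were chosen before the data were examined. Under that rule, passing windows of the same direction at most 2 kb apart were merged into regions, and a region was named by the gene that overlapped its peak window most, or by the nearest gene on each side. For each mutant against WT, the 10 regions highest and the 10 regions lowest by peak difference were named, among those where both mutant arrays lay beyond both WT arrays. For the double mutant against each single mutant and for the interaction, 5 were named in each direction, and where fewer than 10 regions passed in total, the 5 windows with the smallest p in each direction were added as not passing. For each strain's enrichment, the 10 regions with the highest mean were named. Of a list that passed, up to 4 members would have been named. The rule always named rad3, rif1, rad52, cdc25, the histone genes, the centromeres, the mating-type region and the subtelomeres. Regions in repeated sequence are given as uncertain. Single probes, the summary over the right end of chromosome III and the set of windows high in rif1D and lower in the double mutant were chosen after their values were seen.

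The file headers place the arrays on 4 slides. Slide 1 held WT replicate 1 and rad3D replicate 1, and slide 2 held WT replicate 2, rad3D replicate 2, rif1D replicate 2 and double mutant replicate 1. Slide 3 held rif1D replicate 1 and slide 4 held double mutant replicate 2. Slides 1 and 3 were scanned on scan day 1, slide 2 on scan day 2 and slide 4 on scan day 3. Every comparison was therefore also computed within slide 2, with slide as a block (which leaves 1 residual degree of freedom) and with scan day as a block, and rad3D against WT also within slide 1. Slides 3 and 4 held 1 array each, so slide as a block gives those arrays no weight in the differences. Double mutant values then rest on its replicate 1 and rif1D values on its replicate 2. For rad3D against WT the blocked difference equals the pooled one by construction, since slides 1 and 2 each held both strains. Scan day as a block likewise gives double mutant replicate 2, alone on scan day 3, no weight. Windows that passed were selected on the same arrays, so that they keep their sign within a slide is largely built in.

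On simulated data with the fitted spread of each window, 200 of 12,033 windows were changed. For rad3D against WT, limma recovered 95.5% of 2-fold and 20.9% of 1.5-fold changes, with 5.88% of calls false. For rif1D against WT the shares were 94% and 23.9% (5.23% false), for the double mutant against WT 88.1% and 25.4% (3.4% false), against rad3D 91% and 17.9% (7.95% false) and against rif1D 88.1% and 17.9% (4.86% false). For the interaction, 37.3% of 2-fold, 1.49% of 1.5-fold and 98.5% of 4-fold changes were recovered, with 3.19% of calls false. In the simulation of rif1D against WT with 20 lists, fry gave a list raised by 1 on the log2 scale an adjusted p of 0.000381. These simulations drew windows independently, with equal spread on every array and no slide effect. On the real arrays, neighbouring probes correlated at 0.40 to 0.63 and the SD over windows was 0.292 to 0.57. The simulated values therefore do not carry over to the real data, where a window or list that does not pass is not shown to be unchanged.

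The alternatives were normexp background correction (on median signals, since the files give no mean signals, with an offset of 50), loess within arrays, equal spread per array, other filters on dim and outlier spots, GC correction, a replicate block alone and with GC correction, windows of 5 kb, single probes, array weights, a robust and trended prior, only the 2 strains compared, slide as a block, other fold thresholds, camera with preset and estimated correlation, other list definitions, and leaving out each array in turn. Leaving out spots in dim patches (2,177 probes), window medians and scan day as a block were added after seeing the data. The work used R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.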

Results

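Rad52 occupancy along the genome was measured on 8 arrays, 2 for each of the strains WT, rad3D, rif1D and the double mutant rif1D_rad3D, in cells released from a cdc25-22 block into a cycle with no hydroxyurea. Rad52 binds at broken or single-stranded DNA, so its ratio of IP over input can mark places where recombination proteins gather. None of the 8 arrays held a mock or untagged IP, so enrichment unrelated to Rad52 cannot be told apart from Rad52 binding. Values are log2 (IP/input) in windows of 1 kb with the array median at 0; errors are the SD of 2 arrays for levels and the SE of the limma fit for differences. The median IP signal above background was 756 and 456 in the WT arrays, 521 and 590 in rad3D, 449 and 432 in rif1D, and 258 and 1114 in the double mutant. The double mutant's replicate 1 had the weakest IP, with 39,000 of 42,707 probes well above background in that channel against 41,999 to 42,682 on the other arrays. Over all windows, the arrays of a strain correlated at 0.793 in WT, 0.847 in rad3D, 0.811 in rif1D and 0.706 in the double mutant, and arrays of different strains at 0.338 to 0.749.

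The input channel showed the deleted genes. All 14 probes in the coding sequence of rif1 (I: 2,766,370–2,770,572), which encodes a regulator of replication timing, were absent from the input of rif1D (medians of −6.55 and −7.22 relative to the array median) and of the double mutant (−6.87 and −8.47), against −0.43 and −0.45 in WT. Of 26 probes in the coding sequence of rad3 (II: 904,365–911,525), the kinase at the head of the DNA damage checkpoint, 9 were absent in rad3D, between 909,012 and 911,114. In the double mutant 24 were absent, between 904,607 and 911,114. The 17 rad3 probes still present in rad3D lie outside the part deleted there and check nothing. All probes of rad52 and cdc25 were present on every array.

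In WT, Rad52 was highest beside the mating-type locus mat1, over rga7 (II: 2,113,001–2,114,000), at 4.16 ± 0.10 (SD, n = 2). The next regions were over eng1, an enzyme of cell separation (I: 998,001, 3.36 ± 1.073), at I: 4,002,001 (2.56 ± 0.32) and I: 4,692,001 (2.51 ± 0.78) in the part with no gene names, over thi2, a thiamine synthesis gene (II: 3,941,001, 2.33 ± 0.37), and over psf3, a subunit of the GINS replication complex (I: 527,001, 2.17 ± 0.34). The other 4 named regions had means of 1.82 to 2.02: I: 5,238,001, ppk1 within the longest WT region (I: 1,908,001–1,927,000, 19 kb), snoU14 (II: 1,308,001) and the tRNA gene sup9 (III: 1,689,001). Enrichment of at least 1.5-fold that passed limma with BH adjustment covered 620 of 12,033 windows in 302 regions, of which 310 windows lay on chromosome I, 225 on II and 85 on III. Without WT replicate 1 the count was 138.

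The mutants shared the peak over rga7, whose window at II: 2,112,001 stood at 4.11 ± 0.48 in WT, 5.01 ± 0.44 in rad3D, 5.50 ± 0.13 in rif1D and 4.70 ± 1.09 in the double mutant. In rad3D, 574 windows were enriched, and 255 of these were on chromosome III, where the longest region ran for 104 kb (III: 2,325,001–2,429,000) with apl4 at 2.06 ± 0.56 and, in a neighbouring region, the 5S rRNA gene SPRRNA.07 at 2.46 ± 0.60 (III: 2,308,001). In rif1D, 873 windows were enriched, 359 on chromosome I, 358 on II and 156 on III, with eng1 (3.90 ± 0.78), dhp1, a nuclear exoribonuclease (I: 3,356,001, 3.25 ± 0.35), and adh4 (2.39 ± 0.40) among its highest. The window beside mat3-Mc (II: 2,134,001) stood at 2.37 ± 0.16 and the ima1 region (III: 1,891,001) at 2.32 ± 0.30. In the double mutant, 736 windows were enriched, 343 of them on chromosome III, where the longest region spanned 113 kb (III: 2,207,001–2,320,000) and SPCC569.06 (2.58 ± 0.91) and SPRRNA.07 (2.53 ± 1.13) led. The highest regions that several strains had in common included snoU14, which stood at 1.75 to 1.86, psf3 at 1.62 to 2.17, thi2 at 1.75 to 2.33 and the arginine tRNA gene SPATRNAARG.01 at 1.23 to 1.86. By limma with BH adjustment, 188 windows were enriched in all 4 strains and 1,515 in at least 1. WT and rad3D had 287 enriched windows in common where independent lists would share 29.6, and rad3D and the double mutant had 441 against 35.1. Counts depended on single arrays: rad3D had 358 without its replicate 1 and 50 without its replicate 2, rif1D had 357 without its replicate 2, and the double mutant had 446 without its replicate 1 and 1,269 without its replicate 2.

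Several classes of strongly transcribed genes lay above the array median in every strain. The 32 measured 5S rRNA genes had medians of 0.79 in WT, 0.79 in rad3D, 0.55 in rif1D and 0.72 in the double mutant, and the 145 tRNA genes 0.55, 0.51, 0.38 and 0.47. The 63 snRNA and snoRNA genes had medians of 0.53, 0.40, 0.57 and 0.40, the 7 histone genes 0.74, 0.50, 0.85 and 0.76, and the 15 abundantly transcribed genes 0.63, 0.47, 0.54 and 0.54. Ribosomal protein genes (126) had medians of 0.18 to 0.23 and centromeres (15 windows, on II and III only) of 0.44 to 0.61. Subtelomeres (260 windows) lay slightly below the array median in each strain, from −0.24 to −0.10. These levels are descriptions with no test between lists, and IP and input carried fixed dyes, so a dye effect shared by all arrays is not removed from them. With no mock or untagged IP, they may also hold signal that is not from Rad52.

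To ask how loss of the checkpoint kinase changed Rad52 occupancy, rad3D was compared with WT. Ratios over the right end of chromosome III were higher in rad3D, from nsa2, a ribosome biogenesis gene (III: 2,406,001, 2.03 ± 0.26, SE, adjusted p = 0.0214), through pcs60 (2.17 ± 0.42), sac32 (2.01 ± 0.35), tyr1 (1.94 ± 0.35), ecl1 and nnk1 (1.91 ± 0.34), dbp9 (1.85 ± 0.35), adn3 (1.78 ± 0.27) and trm732 (1.72 ± 0.33) to opt3 (III: 2,284,001, 1.54 ± 0.26). The WT means in these 9 windows were all below 0, from −0.75 to −0.03, and the rad3D means were 0.79 to 2.05. One named higher region lay elsewhere: rga7 at II: 2,110,001 rose from 0.42 ± 0.11 to 2.08 ± 0.13, a difference of 1.66 ± 0.19 (adjusted p = 0.0214, limma with BH; 1.68 within slide 2 and 1.664 with slide as a block).

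In rad3D, 9 regions were lower than in WT. At slp1, an activator of the anaphase-promoting complex (I: 995,001), the ratio fell from 2.36 ± 0.65 to 0.51 ± 0.02 (difference −1.85 ± 0.33, adjusted p = 0.0329), and at I: 5,241,001 from 1.99 ± 0.67 to 0.14 ± 0.13 (−1.85 ± 0.28). The neighbours tos4 (I: 1,924,001, −1.57 ± 0.28) and pds5, a cohesin regulator (I: 1,912,001, −1.48 ± 0.22), fell from 1.78 and 1.53 to 0.21 and 0.05. Smaller decreases were at art1 and ulp1 (II: 2,366,001, −1.31 ± 0.25), I: 4,694,001 (−1.22 ± 0.24), exg1, a glucanase (II: 3,516,001, −1.20 ± 0.18), dea2 (II: 175,001, −1.02 ± 0.19) and the first window past mat1 (II: 2,116,001, −0.88 ± 0.16, adjusted p = 0.0352). Next to that window, a probe at II: 2,115,566–2,115,625 was absent from the rad3D input (−7.52 relative to WT), whereas the input of the window itself differed by 0.05. The window beside mat3-Mc (II: 2,134,001), singled out after its values were seen, stood at 1.37 in WT and −0.17 in rad3D and did not pass (−1.54, limma with BH, adjusted p = 0.0581), and no probe there was absent from the input. No named higher or lower window of this comparison passed in all other settings, and the one kept most often was nsa2 (past in 17 of 26). The call was lost more often than kept at pcs60 (past in 12 of 26), the window past mat1 (12 of 26) and I: 4,694,001 (10 of 24). It was kept in 13 of 26 at each of slp1, trm732, art1 and ulp1, and exg1.

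In total 81 windows passed limma with BH adjustment between rad3D and WT, 57 higher and 24 lower, in 20 regions, and 56 of them were on chromosome III; 1,087 had an unadjusted p under 0.05. All 57 and all 24 had the same sign within slide 2 (medians 2.02 and −0.98) and within slide 1 (1.39 and −1.73), against pooled medians of 1.70 and −1.34. Slide as a block gives the pooled differences by construction, since slides 1 and 2 each held both strains. The count was 470 with slide as a block (281 higher and 189 lower), 279 with scan day as a block, 101 after normexp (98 higher and 3 lower) and 0 after loess within arrays. It was 0 without WT replicate 1, 5 without WT replicate 2, 0 without rad3D replicate 2, 0 without either rif1D array, and 273 without either double mutant array. By gene, 0 of 4,790 passed limma and 763 had an unadjusted p under 0.05.

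The list of chromosome III ends, which adjoin the ribosomal DNA arrays, had a median difference of 1.43 between rad3D and WT over its 45 windows, and 22 of these passed over all windows (33 adjusted over the list alone). The list joins both ends, which moved unequally: in the first 50 kb of the left end the mean difference was 0.39 in rad3D and 0.45 in the double mutant, with 0 windows past limma in either, against 1.59 and 2.01 in the last bin of the right end. The list median was 1.77 within slide 2 and 0.99 within slide 1, and slide as a block gives the pooled 1.43 by construction. By limma's fry the BH-adjusted p = 0.115; the adjusted p was 0.308 with an estimated correlation. Subtelomeres of chromosomes I and II had a median of −0.16 (limma fry, BH-adjusted p = 0.115), with 0 of 260 windows past limma. This median was −0.20 within slide 2 and −0.11 within slide 1, and slide as a block again gives the pooled −0.16 by construction. Over all other settings it ranged from −0.2068 to −0.02675. By fry 0 of 20 lists passed and 2 had an unadjusted p under 0.05; camera passed 0 with an estimated and 10 with a preset correlation.

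**Figure D1:**
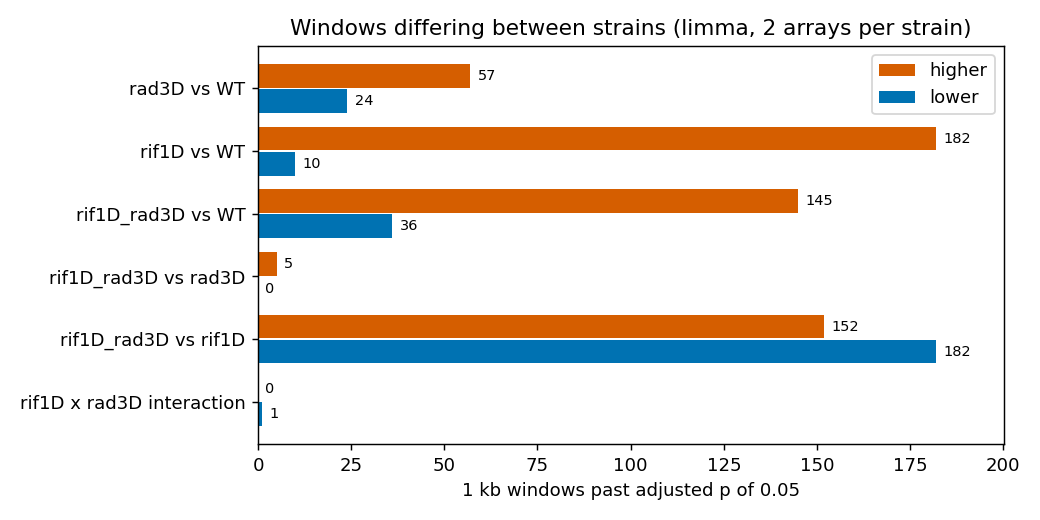
Bars give the number of 1 kb windows (x axis) past an adjusted p of 0.05 (limma, 2 arrays per strain) in each comparison (y axis), higher in orange and lower in blue. rif1D had 182 windows above WT and 10 below, and the double mutant differed from rad3D in 5 windows.

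To ask what loss of Rif1 did, rif1D was compared with WT. The highest rise was over dhp1 and its neighbours (I: 3,337,001–3,361,000, 24 kb), where the dhp1 window went from 0.46 ± 0.29 to 3.25 ± 0.35, a difference of 2.79 ± 0.22 or 6.92-fold (adjusted p = 0.00025). Next came rga7 beside mat1 (II: 2,111,001, 2.64 ± 0.42), SPCC737.04 near ima1 (III: 1,892,001, 2.15 ± 0.22) and adh4, an alcohol dehydrogenase (I: 157,001, 1.90 ± 0.23). Past mat1, II: 2,116,001 rose from 0.94 ± 0.19 to 2.75 ± 0.10 (1.81 ± 0.16, adjusted p = 0.000326). The input of that window was lower by a log2 difference of −1.002, which made up 55.4% of the gain in the ratio. The other named rises, with differences of 1.52 to 1.72, were between snp27 and adh1 (III: 1,590,001), at I: 4,355,001 and I: 4,217,001, over leu1, a leucine synthesis gene (II: 1,975,001), and over SPCC576.19C (III: 2,081,001).

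In rif1D, 8 regions were lower, by smaller amounts. The largest was I: 4,694,001 (−1.25 ± 0.24, adjusted p = 0.0254, limma with BH), followed by I: 5,259,001 (−1.03 ± 0.21), which passed in only 11 of 23 other settings and ranged there from −1.28 to −0.29. The rest lay between −0.94 and −0.71: tlh1 at the left end of chromosome I, in repeated sequence and therefore uncertain (−0.94 ± 0.17), I: 4,170,001 (−0.88 ± 0.16), tom20, a mitochondrial import receptor (−0.87 ± 0.18), SPBPB10D8.02C (−0.80 ± 0.17), cdr1, a mitotic kinase (−0.74 ± 0.15), and psy2 (−0.71 ± 0.15). Most of these calls were also unstable. Under the other settings SPBPB10D8.02C and psy2 passed in 13 of 26 each, cdr1 in 14 of 26, tom20 in 15 of 26 and I: 4,170,001 in 15 of 24. I: 4,694,001 passed in 18 of 24 and tlh1 in 20 of 26.

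In all, 192 windows passed limma with BH adjustment, 182 higher and 10 lower, in 58 regions, with 96 windows on chromosome I, 54 on II and 42 on III; 1,486 had an unadjusted p under 0.05. All 182 and all 10 kept their sign within slide 2 (medians 1.20 and −0.75) and within scan day 1 (0.99 and −0.95), against pooled medians of 1.09 and −0.88 and of 1.17 and −0.81 with slide as a block. Values and counts with slide as a block rest on rif1D replicate 2 alone, since replicate 1 was the only array on slide 3. The count was 646 with slide as a block (513 higher and 133 lower), 482 with scan day as a block, 429 with equal spread per array (356 higher and 73 lower) and 9 after normexp, all higher. It was 57 and 65 without WT replicates 1 and 2, 127 and 37 without rif1D replicates 1 and 2, 121 without either rad3D array and 473 without either double mutant array. By gene, 108 rose and 6 fell.

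The mating-type region had a median difference of 0.58 between rif1D and WT over 24 windows, with 6 higher over all windows and 11 adjusted over the list alone. The median was 0.84 within slide 2, 0.43 within scan day 1 and 0.81 with slide as a block. By limma's fry the BH-adjusted p = 0.193; the adjusted p was 0.676 with an estimated correlation. Subtelomeres had a median of −0.17 (limma fry, BH-adjusted p = 0.122, and 0.424 with an estimated correlation; −0.19 within slide 2, −0.16 within scan day 1 and −0.17 with slide as a block), with 2 of 260 windows lower. By fry 0 of 20 lists passed and 2 had an unadjusted p under 0.05; camera passed 0 with an estimated and 7 with a preset correlation.

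**Figure D2:**
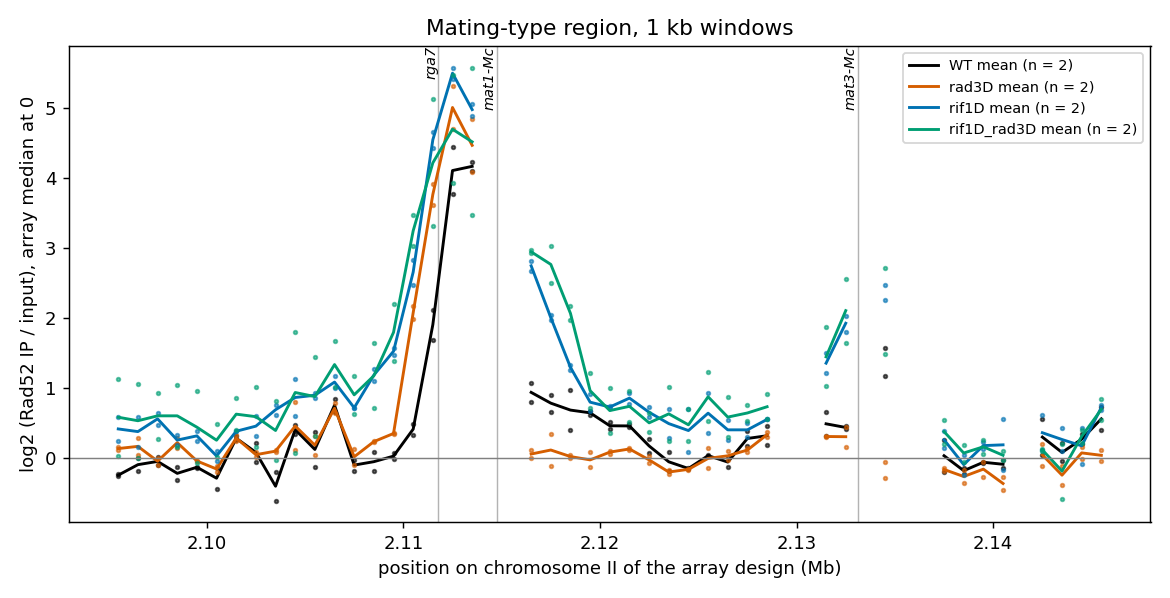
The y axis gives log2 (IP/input) in 1 kb windows along the mating-type region of chromosome II (x axis, Mb), with lines for strain means (n = 2), dots for single arrays and gaps where windows are missing. In the first window past mat1, rif1D (2.75) and the double mutant (2.95) lie above WT (0.94) and rad3D lies at 0.06; lower input in rif1D and the double mutant accounts for 55.4% and 58% of their gain there.

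The double mutant was compared with WT to see the combined loss. Beside mat1, rga7 (II: 2,110,001) rose from 0.42 ± 0.11 to 3.25 ± 0.31, a difference of 2.83 ± 0.19 (adjusted p = 0.000137). A stretch of 104 windows at the right end of chromosome III (III: 2,325,001–2,429,000) was higher throughout, with its peak at nnk1 (2.63 ± 0.43, adjusted p = 0.0108). Along the same chromosome end, gst2 (2.36 ± 0.42), taf13 (2.30 ± 0.45), csl4 (2.07 ± 0.44), pdi5 (2.02 ± 0.44), pgm2 (1.998 ± 0.42) and SPCC569.02C (1.99 ± 0.30) were higher too. Several of these rested on double mutant replicate 1: without it the difference was 1.43 at taf13, 1.251 at pgm2, 1.20 at pdi5 and 1.16 at csl4, and the last 3 did not pass. Under the other settings pdi5 passed in 9 of 26 and csl4 in 12 of 26. At the mating-type region, the first window past mat1 rose by 2.01 ± 0.16 (adjusted p = 0.000321), with 58% of the gain from lower input, and mat3-Mc (II: 2,132,001) rose by 1.66 ± 0.25.

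Lower in the double mutant than in WT were I: 5,241,001 (−1.89 ± 0.28, adjusted p = 0.00772, limma with BH), ppk1 (I: 1,910,001, −1.41 ± 0.29), I: 5,260,001 (−1.38 ± 0.20), slp1 (I: 994,001, −1.35 ± 0.29), tos4 (I: 1,922,001, −1.31 ± 0.26), I: 5,268,001 (−1.06 ± 0.19), I: 5,236,001 (−0.99 ± 0.19), tom20 (−0.98 ± 0.18), I: 4,672,001 (−0.95 ± 0.20) and I: 4,691,001 (−0.92 ± 0.18). The ppk1, slp1 and tos4 windows stood at 1.501 to 1.62 in WT and at 0.12 to 0.27 in the double mutant. The slp1 window again lies in the WT region that peaks at eng1. Without WT replicate 1 the difference was −0.85 at slp1 and −0.82 at tos4, and within slide 2 it was −0.77 and −0.71. Under the other settings slp1 passed in 7 of 26, and I: 4,672,001 and I: 4,691,001 in 11 of 24 each.

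In all, 181 windows passed limma with BH adjustment, 145 higher and 36 lower, in 30 regions, and 136 of them were on chromosome III; 1,173 had an unadjusted p under 0.05. All kept their sign within slide 2 (medians 2.62 and −0.86), against pooled medians of 2.05 and −1.05 and of 2.43 and −0.99 with slide as a block. Slide or scan day as a block gives double mutant replicate 2 no weight. Values and counts under these blocks therefore rest on its replicate 1, the array with weak IP. The count was 1,111 with slide as a block (593 higher and 518 lower), 721 with scan day as a block, 346 with equal spread per array (240 higher and 106 lower) and 147 after normexp, all higher. It was 4 and 10 without WT replicates 1 and 2, 103 without either rif1D array and 1,056 without double mutant replicate 2. By gene, 54 rose and 5 fell.

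Chromosome III ends had a median difference of 1.73 in the double mutant against WT, with 28 of 45 windows higher over all windows and 36 adjusted over the list alone. The median was 1.98 within slide 2 and 1.78 with slide as a block. By limma's fry the BH-adjusted p = 0.112; the adjusted p was 0.432 with an estimated correlation. The mating-type region had a median of 0.63, with 7 windows higher over all and 12 adjusted over the list alone (limma fry, BH-adjusted p = 0.121, and 0.432 with an estimated correlation). Its median was 1.06 within slide 2, which holds only double mutant replicate 1, and 1.05 with slide as a block. Over all other settings it ranged from 0.275 to 1.126. The region's level was 1.22 and 0.637 on double mutant replicates 1 and 2, against 0.437 and 0.396 in WT. By fry 0 of 20 lists passed and 2 had an unadjusted p under 0.05; camera passed 0 with an estimated and 6 with a preset correlation.

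The changes of rad3D and of the double mutant against WT correlated over windows at r = 0.724 with a covariance of 0.0788. Simulated unchanged strains, compared with the same simulated WT arrays, gave 0.501 and 0.0185. The real WT arrays were not used there, and windows were drawn independently with equal spread on every array. The simulated values therefore leave out the correlation between windows and the unequal spread of the real WT arrays. The SD over windows was 0.421 on WT replicate 1 and 0.292 on WT replicate 2. Of the windows, 57 were higher in both where independent lists would share 0.687, and 10 were lower in both against 0.0718. The changes of rif1D and of the double mutant had r = 0.411 (simulated 0.5) and a covariance of 0.0441 (simulated 0.0185), with 7 windows higher in both against 2.19 and 6 lower in both against 0.0299. Those of rad3D and rif1D had r = 0.152 (simulated 0.501) and a covariance of 0.0141, below the simulated 0.0185, with 1 window higher in both against 0.862 and 1 lower in both against 0.0199. In simulated unchanged strains the mean number of windows past in both was 0 for rad3D and the double mutant, 0 for rif1D and the double mutant, and 0.02 for rad3D and rif1D. The 2 WT arrays were not split, since each comparison would have rested on 1 of them, so part of the excess may come from the shared controls, and genome windows are not independent replicates.

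**Figure D3:**
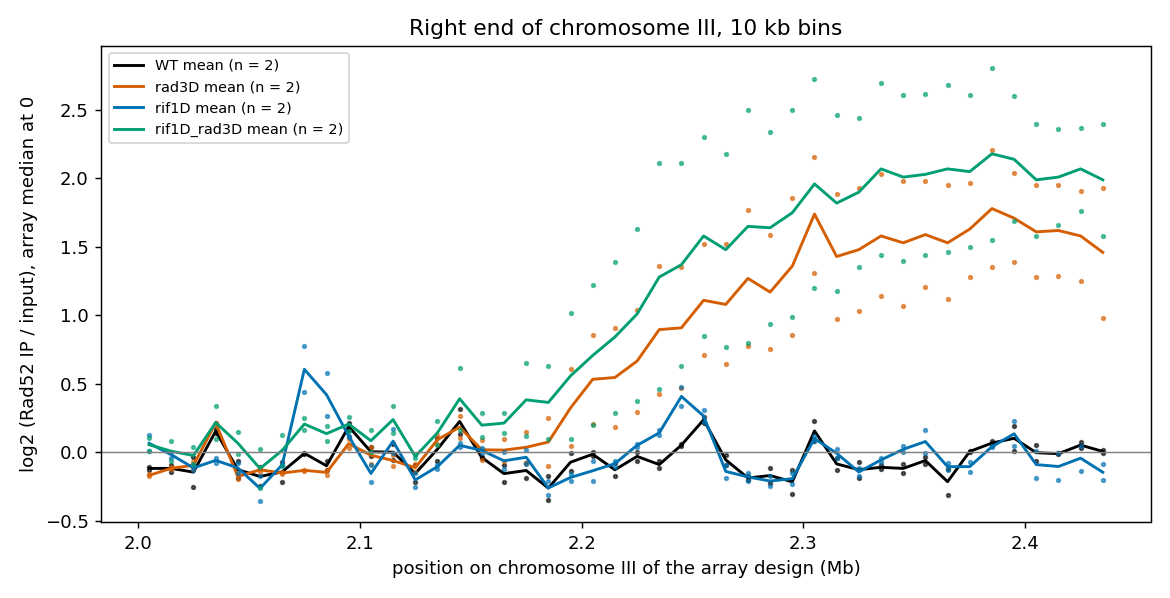
The y axis gives log2 (IP/input) in bins of 10 kb along the right end of chromosome III (x axis, Mb), with lines for strain means (n = 2) and dots for single arrays. From 2,250,001 to 2,433,000 the median difference from WT is 1.54 in rad3D, 1.98 in the double mutant and 0.01 in rif1D, and the arrays of the double mutant lie far apart.

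The summary over the right end of chromosome III was chosen after the values were seen. Over its 173 windows (III: 2,250,001–2,433,000), which include opt3, nnk1 and nsa2, the median difference from WT was 1.54 in rad3D (quartiles 1.39 and 1.73), 1.98 in the double mutant (1.75 and 2.18) and 0.01 in rif1D. The rise began gradually: in bins of 50 kb from 2.15 Mb on, rad3D differed from WT by 0.22, 0.75, 1.27, 1.61, 1.67 and 1.59, and the double mutant by 0.47, 1.08, 1.69, 2.01, 2.12 and 2.01. The arrays of a strain lay far apart in the early bins. In the bin from 2,200,001, replicates 1 and 2 stood at 0.317 and 1.1 in rad3D and at 1.69 and 0.392 in the double mutant. Where the rise starts is therefore uncertain. Input differed by a median of −0.06 in rad3D and −0.11 in the double mutant. Of the 173 windows, 56 passed limma in rad3D and 136 in the double mutant.

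The double mutant was set against rad3D to ask what loss of Rif1 added when Rad3 was missing. All 5 windows that passed lay in the mating-type region, where the rad3D strain itself differed: its input lacked a probe beside mat1 (−7.52 relative to WT, against −1.22 in the double mutant). The rad3 deletions differed too, with 9 of 26 coding probes absent in rad3D and 24 in the double mutant, so the comparison is not of rif1 alone. The first window past mat1 (II: 2,116,001) stood at 0.06 ± 0.08 in rad3D and 2.95 ± 0.03 in the double mutant, a difference of 2.89 ± 0.16 (adjusted p = 1.29e-05, 2.85 within slide 2 and 2.94 with slide as a block), and the window beside mat3-Mc (II: 2,134,001) at −0.17 ± 0.16 and 2.10 ± 0.87, a difference of 2.27 ± 0.31 (adjusted p = 0.0431). The input of the mat1 window was lower by −1.21 in the double mutant. No decrease passed, and the 5 with the smallest p were car1 at −0.99 ± 0.17 (adjusted p = 0.203), then cmk1 at −0.87, sos7 at −0.81, SPBC713.09 at −0.71 and paf1 at −0.71 (adjusted p = 0.443 for each of the last 4).

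With limma and BH adjustment, 979 windows had an unadjusted p under 0.05 between the double mutant and rad3D against the 5 that passed. The pooled median of the 5 was 2.27, with 2.68 within slide 2 and 2.86 with slide as a block. Values and counts with slide or scan day as a block rest on double mutant replicate 1 alone. The count was 1,145 with slide as a block (549 higher and 596 lower), 350 with scan day as a block, 7 with equal spread per array (6 higher and 1 lower), 715 without double mutant replicate 2, and 3 without any 1 of the WT, rad3D and rif1D arrays. By gene, 1 rose and 692 had an unadjusted p under 0.05. In the mating-type region the median difference was 0.62, with 5 of 24 windows higher and 18 adjusted over the list alone; limma's fry gave a BH-adjusted p = 0.147 (adjusted p = 0.276 with an estimated correlation). The median was 1.11 within slide 2, which holds only double mutant replicate 1, and 1.142 with slide as a block. Over all other settings it ranged from 0.4108 to 1.16. By fry 0 of 20 lists passed and 4 had an unadjusted p under 0.05. The others were subtelomeres (median 0.13, limma fry, BH-adjusted p = 0.147), meiotic genes (−0.06, adjusted p = 0.17) and G1/S genes (0.02, adjusted p = 0.17). Camera passed 0 with an estimated and 6 with a preset correlation.

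The double mutant was set against rif1D to ask which Rad52 regions of rif1D differed when rad3 was missing too. Of the 182 windows higher in rif1D than in WT, 112 were lower in the double mutant than in rif1D, and only 7 of the 182 passed as higher in the double mutant than in WT, among them the first window past mat1 (2.75 in rif1D and 2.95 in the double mutant). The cnt6 window next to dhp1 (I: 3,355,001) stood at 2.78 ± 0.23 in rif1D and 0.35 ± 0.19 in the double mutant, a difference of −2.43 ± 0.18 (adjusted p = 0.000248). Likewise lower were slp1 (I: 994,001, −2.24 ± 0.29), adh4 (I: 156,001, −2.15 ± 0.24), the window between snp27 and adh1 (III: 1,590,001, −1.996 ± 0.17) and the one between ima1 and SPCC737.04 (III: 1,891,001, −1.97 ± 0.18). The slp1 window lies within the rif1D region that peaks at eng1 (I: 987,001–1,004,000). Higher in the double mutant was the right end of chromosome III, with are2, a sterol acyltransferase (2.60 ± 0.40, adjusted p = 0.00453), alr1 (2.22 ± 0.49), SPCC569.02C (2.137 ± 0.30) and pca1, a metacaspase (1.95 ± 0.46), and at the other end of that chromosome SPCC757.05C (III: 53,001, 0.78 ± 0.18). Without double mutant replicate 1 the difference was 0.99 at pca1, which did not pass, and 1.22 at alr1. Under the other settings pca1 passed in 10 of 26 and SPCC757.05C in 12 of 26.

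Between the double mutant and rif1D, 334 windows passed limma with BH adjustment, 152 higher in 6 regions and 182 lower in 48 regions; 172 lay on chromosome III, 108 on I and 54 on II, and 1,166 had an unadjusted p under 0.05. All kept their sign within slide 2, where the medians were 2.64 and −1.23 against pooled medians of 2.01 and −1.08. Slide as a block gave the slide 2 values by construction, since it leaves weight only on rif1D replicate 2 and double mutant replicate 1. Scan day as a block also gives double mutant replicate 2 no weight. The count was 1,029 with slide as a block (434 higher and 595 lower), 680 with scan day as a block and 154 after normexp (137 higher and 17 lower). It was 216 and 67 without rif1D replicates 1 and 2 and 780 without double mutant replicate 2. By gene, 57 rose and 86 fell. For the 112 windows higher in rif1D than in WT and lower in the double mutant, independent lists would share 2.75, and simulated unchanged strains shared 0.01. These comparisons share the rif1D arrays with opposite sign (r = −0.438, simulated −0.5; covariance −0.0476, simulated −0.0184), so part of the excess may come from the shared rif1D arrays. Over these 112 windows, chosen for those differences, the median ratio was 1.38 in rif1D, 0.16 in WT, −0.03 in rad3D and 0.20 in the double mutant.

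Chromosome III ends had a median difference of 1.96 between the double mutant and rif1D, with 29 of 45 windows higher over all windows and 39 adjusted over the list alone. The median was 2.31 within slide 2 and with slide as a block. By limma's fry the BH-adjusted p = 0.0935; the adjusted p was 0.231 with an estimated correlation. Subtelomeres had a median of 0.14 (limma fry, BH-adjusted p = 0.102; 0.19 within slide 2), and 0 of 260 windows passed. By fry 0 of 20 lists passed and 2 had an unadjusted p under 0.05; camera passed 0 with an estimated and 6 with a preset correlation.

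**Figure D4:**
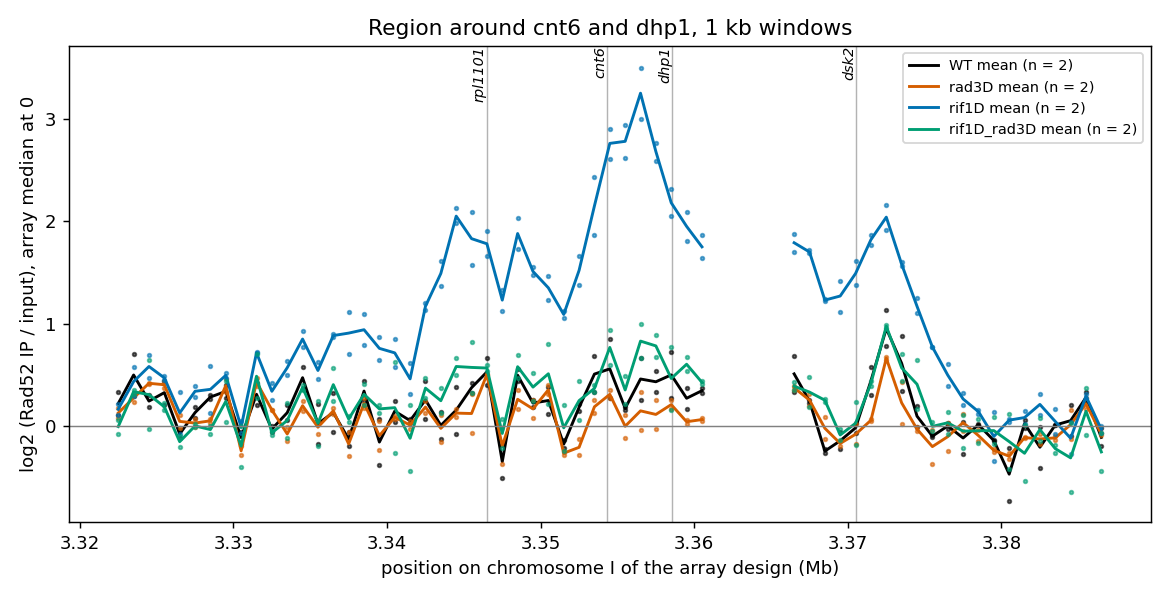
The y axis gives log2 (IP/input) in 1 kb windows around cnt6 and dhp1 on chromosome I (x axis, Mb), with lines for strain means (n = 2), dots for single arrays and gaps where windows are missing. At cnt6, rif1D stands at 2.78 while the double mutant (0.35), WT (0.17) and rad3D (0.00) lie near 0.

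The interaction asked whether the effect of rif1 deletion differed with and without rad3. It takes the rad3 deletions of rad3D (9 of 26 coding probes absent) and the double mutant (24 absent) as equal, and these may be different alleles. At cnt6 (I: 3,355,001) the ratio was 0.17 ± 0.02 in WT, 0.00 ± 0.16 in rad3D, 2.78 ± 0.23 in rif1D and 0.35 ± 0.19 in the double mutant, and the interaction was −2.25 ± 0.25 (adjusted p = 0.0197, limma with BH; −2.13 within slide 2 and −2.22 with slide as a block). Of the other windows below 0, the 4 with the smallest p did not pass: snp27 and adh1 (−1.84, adjusted p = 0.0593), and dhp1 (−2.11), ima1 and SPCC737.04 (−1.71) and adh4 (−1.68), each with adjusted p = 0.0809. Of the windows above 0, none passed, and the 5 with the smallest p were SPBC23G7.10C past mat1 (1.43, adjusted p = 0.121), SPBPB10D8.02C (1.20, 0.156), and I: 4,694,001 (1.66), cdr1 (1.15) and the first window past mat1 (1.08), each at 0.164.

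For the interaction, 1 window passed limma and 654 had an unadjusted p under 0.05. With slide or scan day as a block, the double mutant is represented by its replicate 1 alone. The count was 184 with slide as a block (58 higher and 126 lower), 36 with scan day as a block, 33 with equal spread per array (6 higher and 27 lower), 6 after loess and 0 after normexp. It was 0 without any 1 of the WT, rad3D and rif1D arrays and 10 and 41 without double mutant replicates 1 and 2. By gene, 11 of 4,790 passed, all lower, and 397 had an unadjusted p under 0.05.

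Among the histone genes, hta1 was at 1.08 ± 0.16 in WT, 0.68 ± 0.01 in rad3D, 0.87 ± 0.08 in rif1D and 0.77 ± 0.09 in the double mutant, and htb1 at 0.97, 0.57, 0.91 and 0.85. The genes hhf2 (0.75, 0.53, 1.47 and 0.82), hht2 (0.74, 0.45, 1.097 and 0.62), hht3 (0.50, 0.09, 1.04 and 0.69), hhf3 (0.18, 0.02, 0.68 and 0.57) and the H2A.Z gene pht1 (0.57, 0.53, 0.68 and 0.69) are given in the same order; hhf3 in WT and hhf3, hht3 and hht2 in rad3D did not pass limma against the array median. No histone gene passed limma with BH adjustment in any of the 5 comparisons, the lowest adjusted p being 0.139 for hhf2 in rif1D against WT. At rad52 the means were 0.17, 0.35, 0.17 and 0.18, and at cdc25 0.17, 0.15, 0.11 and 0.02. The centromeres of II and III (15 windows) differed by medians of −0.10 to 0.14 over the 5 comparisons (limma fry, lowest BH-adjusted p = 0.586).

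None of the other lists passed fry with BH adjustment in any comparison. Medians of the differences ranged from −0.19 to 0.06 for tRNA genes (lowest adjusted p = 0.641), −0.21 to 0.22 for 5S rRNA genes (0.542), −0.16 to 0.05 for snRNA and snoRNA genes (0.257), −0.30 to 0.36 for histone genes (0.257), −0.13 to 0.10 for abundantly transcribed genes (0.264) and −0.08 to 0.02 for ribosomal protein genes (0.483). Mitochondrial DNA ranged from −0.42 to 0.00 (0.681), with strain medians of −0.51 to −0.07, and AT-rich islands, many of which hold replication origins, from −0.05 to 0.07 (0.591). Convergent and divergent intergenic regions ranged from −0.09 to 0.02 and from −0.02 to 0.06 (both 0.257), LTR and Tf2 elements from 0.04 to 0.08 (0.483) and wtf genes from 0.02 to 0.19 (0.562). G1/S genes ranged from −0.12 to 0.03 (0.17), heat-shock genes from −0.06 to 0.05 (0.517), meiotic genes from −0.06 to 0.07 (0.17) and long genes from −0.05 to 0.01 (0.592).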

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

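Of the tests below, the one on compressed ratios in the double mutant was set before its result was seen; those on input, slide, single arrays and the mat1 sequence were chosen only after. The results listed first passed the interaction test of limma, which compares the effect of rif1 deletion with and without rad3. The rad3 deletions of rad3D and the double mutant differed (9 and 24 of 26 coding probes absent). A difference of allele or strain therefore cannot be told apart from a dependence on rad3. One window passed, cnt6 at I: 3,355,001 (−2.253), and it passed in 17 of 25 other settings. The calls by gene were not repeated under other settings. By gene, the interaction on the log2 scale was −1.71 at cnt6, −1.681 at SPAC26A3.11, −1.566 at SPCC737.04, −1.426 at dhp1, −1.369 at atg44, −1.329 at rpl1101, −1.305 at dsk2, −1.298 at smb1, −1.296 at nsp1, −1.286 at bud23 and −1.246 at ima1, with BH-adjusted p-values of 0.0102 to 0.0228 and SE of 0.139 to 0.217. Of these 11 genes, 9 lie on I between 3,344,732 and 3,371,384 and are therefore not independent; in rif1D their means were 1.37 to 2.74, in the double mutant 0.15 to 0.76, in WT −0.07 to 0.45 and in rad3D 0.00 to 0.37. The other pair, SPCC737.04 and ima1, lies on III.

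The first pattern is that part of the regions high in rif1D, 112 windows of 182, were lower in the double mutant. Since these windows were chosen for that difference, 182 windows were picked on replicate 1 of rif1D and WT alone and measured on other arrays. There, double mutant replicate 2 lay below rif1D replicate 2 by a median difference of −0.7694, which argues against the weak IP of replicate 1 as the whole cause, and the median within slide 2 was −0.5549 (quartiles −1.22 and −0.0913), which argues against a slide difference as the whole cause. Ratios compressed throughout the double mutant would lower all strong sites. The 282 windows enriched in WT and rad3D that lay outside these 112 and outside the right end of chromosome III had a median difference of 0.05756. That value averages both double mutant arrays, whose SD over windows was 0.57 in replicate 1 and 0.311 in replicate 2. It therefore cannot test compression in replicate 2 alone. Slide 2 holds only replicate 1, the array with weak IP, so no single test is free of both limits. What stays open is compression in replicate 2, a dependence on Rad3 of Rad52 binding in these regions, or a different share of cells in S phase at harvest, which was not tested.

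The second pattern is the higher ratio over the right end of chromosome III in rad3D and the double mutant. Lower input is argued against, since the more negative of the median input differences was −0.1127, and a slide difference, since the lowest median difference between arrays of 1 slide was 1.124. For the double mutant, the weak IP of replicate 1 is argued against as the whole cause, since replicate 2 alone differed from WT by a median of 1.406. The first 50 kb of the left end, also next to ribosomal DNA, differed from WT by less: 0.39 in rad3D, 0.45 in the double mutant and 0.01 in rif1D. In the bins of 50 kb from 50,001 and 100,001 the differences were 0.37 and 0.31 in rad3D and 0.49 and 0.38 in the double mutant. In rif1D they were 0.09 and 0.13. In these left bins 0 windows passed limma in rad3D or the double mutant. The rad3 deletions differed (9 and 24 of 26 coding probes absent), which speaks against a rad3 allele shared by descent but not against another shared property. What stays open is an effect of rad3 loss that is larger at the right end, or such a property of the strains. Neither was tested.

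The third pattern is the low ratio beside mat1 in rad3D. The probe next to mat1 had an input difference of −7.518 against WT on the rad3D arrays, which is consistent with sequence beside mat1 that is missing or changed in the rad3D strain. A higher input in the tested window itself is argued against by its difference of 0.04956. The window beside mat3-Mc, where no probe was absent, was also low in rad3D (−1.54 against WT, limma with BH, adjusted p = 0.0581, not past), so a change confined to mat1 may not be the whole cause. What stays open is whether loss of Rad3 or a difference in the mating-type region gave the lower Rad52 ratio; the double mutant, which also lacks rad3, stood at 2.95 in that window and did not lack the probe.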

How the results depend on the processing

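The counts of differing windows depended strongly on the choices made, so the number of changed windows is uncertain. Of the repeated tests of named differing windows over all settings, 1,231 passed again, 561 no longer passed and 0 reversed. The absence of reversals is largely built in, since these windows were picked for the largest differences on the same arrays. Except for the interaction, they also had every array of 1 strain beyond those of the other. Leaving out 1 array therefore could not reverse them. Signal over background limits what can be seen: input well above background was required on all arrays, but the IP was weak on double mutant replicate 1, so low ratios there are the least precise. Each strain had 2 arrays, and leaving 1 out leaves a single array in that strain. Unless stated, the cause was not tested. Settings marked as added were chosen after the data were seen.

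Normexp background correction gave 101 enriched windows in WT, 9 differing windows for rif1D against WT, 3 for the double mutant against rad3D, 154 against rif1D and 0 for the interaction, and 1 list each for rad3D against WT, the double mutant against WT and against rif1D. Loess within arrays gave 0 windows for rad3D against WT and 6 for the interaction. Equal spread per array gave 324 windows for rad3D, 429 for rif1D and 346 for the double mutant against WT and 33 for the interaction, with 3 lists for rad3D against WT and 1 each for the double mutant against WT and against rif1D. With no filter on dim probes the interaction had 3 windows, and with both channels above background 2.

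Windows of 5 kb are fewer by construction and gave 70, 71, 145 and 96 enriched in WT, rad3D, rif1D and the double mutant, 26 differing for rad3D against WT (8 higher and 18 lower), 51 for the double mutant against WT, 1 against rad3D, 126 against rif1D and 15 for the interaction. Single probes, of which there are more by construction, gave 2,087, 1,968, 2,677 and 2,519 enriched, 0 differing for rad3D against WT, 91 for rif1D, 378 for the double mutant, 10 against rad3D, 575 against rif1D and 0 for the interaction. A lower fold threshold for enrichment gave 1,060, 998, 1,472 and 1,199 windows, and of 2-fold 176, 234, 298 and 315. A robust and trended prior gave 3 for the double mutant against rad3D and 5 for the interaction. Array weights gave 317 for rad3D and 302 for rif1D against WT and 2 for the interaction. Fits of only the 2 strains compared gave 286 for rad3D and 480 for rif1D against WT, and 2 and 185 for the double mutant against rad3D and rif1D. Camera with a preset correlation gave 10, 7, 6, 6 and 6 lists, and subtelomeres of 50 kb gave 2 lists for the double mutant against rif1D.

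With slide as a block, the counts were 470 for rad3D, 646 for rif1D and 1,111 for the double mutant against WT, 1,145 and 1,029 for the double mutant against rad3D and rif1D, 184 for the interaction, and 1 list for the double mutant against rad3D. With scan day as a block (added), they were 279, 482, 721, 350 and 680, and 36 for the interaction. Both blocks give double mutant replicate 2 no weight, and slide as a block gives rif1D replicate 1 none. The larger counts under them are therefore not firmer results. The shift of G1/S genes between the double mutant and rad3D, a median of 0.02, became −0.01524 with scan day as a block and ranged from −0.003243 to 0.09839 when 1 array was left out, the lowest without double mutant replicate 2.

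A replicate block, which treats equal replicate numbers as pairs, gave 0 windows for rad3D against WT and 2 for the interaction, and with GC correction 0 for rad3D, 94 for rif1D and 117 for the double mutant against WT and 2 for the interaction. The deviations of arrays of equal number correlated at −0.35 to 0.125 over the 6 pairs of strains, 1 of them above 0.1. In WT, rad3D and rif1D, replicate 1 was scanned on scan day 1 and replicate 2 lay on slide 2. In the double mutant it was replicate 1 that lay on slide 2. Its deviations correlated at −0.35 with rad3D, −0.173 with rif1D and 0.0768 with WT. Numbers and slides are therefore mixed, and the check cannot tell whether equal numbers mark pairs.

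Leaving out 1 array gave 138 to 632 enriched windows in WT, 50 to 612 in rad3D, 357 to 891 in rif1D and 446 to 1,269 in the double mutant. Differing windows ranged from 0 to 273 for rad3D, 37 to 473 for rif1D and 4 to 1,056 for the double mutant against WT, from 3 to 715 for the double mutant against rad3D, from 67 to 780 against rif1D and from 0 to 41 for the interaction. Lists ranged from 0 to 1 for rif1D against WT, the double mutant against WT and the double mutant against rad3D, and stayed at 0 for rad3D against WT and the double mutant against rif1D.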

Other observations

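No value below was planned before the data were seen, and none of the paragraphs reports a test. The strains labelled as lacking rad3 differed in how much of the gene was missing: 9 of 26 coding probes were absent in rad3D and 24 of 26 in the double mutant. Only 1 probe outside the deleted genes was absent from the input of both arrays of a strain, the one at II: 2,115,566–2,115,625 beside mat1 in rad3D (−6.45 and −5.84 relative to the array median). At the same probe, the input differed from WT by −0.68 in rif1D and −1.22 in the double mutant. From there to 2,117,865, all 9 probes had lower input than WT in rif1D (median −0.68, from −1.44 to −0.22) and in the double mutant (median −0.95, from −1.73 to −0.53), and the next 29 probes up to 2,125,800 had medians of −0.02 and −0.08.

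In bins of 200 kb on chromosome I, rad3D lay at 0.19 and 0.23 on its arrays from 800,001 to 1,000,000 and at 0.18 and 0.21 from 1,600,001 to 1,800,000, against 0.08 and 0.07, and 0.01 and 0.01, in WT. The double mutant, which also lacks rad3, lay at −0.0218 and 0.0148, and at −0.0939 and −0.00138, in these bins. On chromosome II from 1,200,001 to 1,400,000, rad3D lay at 0.17 and 0.30 (WT 0.00 and 0.03). There rif1D lay at 0.132 and 0.199 and the double mutant at 0.109 and 0.0589. At II: 1,800,001 to 2,000,000 rif1D lay at 0.37 and 0.50 (WT 0.06 and 0.06) and the double mutant at 0.0758 and 0.0358. At the left end of chromosome II, the first bin stood at −0.26 and −0.28 in rad3D against 0.01 and 0.01 in WT. It stood at −0.138 and −0.132 in rif1D and at −0.186 and −0.115 in the double mutant.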
